A study of Rattus norvegicus with 12 samples.

How the data were processed

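The deposited value table was used, with 1 column per array and 8799 probe sets, of which 59 were controls. Its unit was read as intensity from the deposited values themselves, which are on a linear scale and of which 21.6 to 25.6% were negative on each array. The software, background step and scaling behind the table are not given in the sources used here. After removal of the lowest and highest 2% of values, the array means lay between 1001.52 and 1002.08, so the values were taken as already scaled and were not normalized again. No pair of arrays shared more than 0.114% identical values, and 0 columns were left unused.

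The planned floor, the 10th percentile of all values, was negative and has no logarithm, so its absolute value, 90.91 (log2 6.51), was used, and lower values were raised to it before log2. Because of this, the alternative floor at the 5th percentile (182.2) was higher than the main one, and that at the 25th percentile (4.2) was much lower. Probe sets with a mean log2 under the 30th percentile (6.54) were left out, 2622 in number, and 6118 were tested. Between 13.4 and 21.1% of the tested values on each array were at the floor. A change is given as "at least" where the lower group had 1 or 2 untreated or 3 or more treated arrays at the floor and every array of the other group lay above it. A rising slope is given as "at least" where its 2 h array alone was at the floor.

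Probe sets were named from the array annotation, whose symbols were checked through gene numbers: 7006 named 1 gene, 308 several and 1426 none, and of 6985 matched symbols 0 had changed. Together they named 4737 genes. Probe sets of several genes or of none were tested but are not named.

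Each treatment was compared with the untreated arrays with limma (lmFit, then eBayes with a variance trend) on all 12 arrays, with 9 residual degrees of freedom. Butyrate was compared with aspirin on the 10 treated arrays with time as a block (4 degrees of freedom), and slopes over log2 hours were fitted to the same arrays (6 degrees of freedom). Adjusted p-values are those of Benjamini and Hochberg, with a threshold of 0.05. The number of arrays limits the precision. The groups, contrasts, floor percentile, filter, thresholds, lists, rule for named genes and most alternatives were chosen before the data were examined.

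There were 29 gene lists (796 members on the array), written from general knowledge: cell cycle and DNA replication, cyclin-dependent kinase inhibitors, beta-catenin signalling, immediate-early factors, apoptosis, histones and chromatin, intestinal differentiation, xenobiotic metabolism, amino acid and unfolded protein response, heat shock, cholesterol and fatty acid synthesis, fatty acid and ketone body oxidation, glycolysis, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis, proteasome, antigen presentation and interferon, NF-kappaB targets, actin and adhesion, extracellular matrix, neuronal genes, metallothioneins, lysosome, growth factor signalling, and markers of fibroblasts, blood and immune cells, endothelium and hepatocytes. Each gene was represented by its brightest probe set. Short names below stand for whole lists. The histone list also holds chromatin regulators, the kinase inhibitor list growth arrest genes and the heat shock list chaperones. Lists were tested against all other genes with camera at its preset correlation of 0.01, again with an estimated correlation, and by themselves with fry, whose p tests either a change one way on balance or changes in either direction. Adjustment was over the 29 lists of a comparison.

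Genes named in the report were the 12 largest rises and 12 largest falls of each treatment comparison among called probe sets that named 1 gene and went the same way on every array, with 1 probe set per gene, filled up to 6 with uncalled values where fewer were called. To these were added the 5 steepest slopes in each direction, up to 4 called members of each list, and Cdkn1a, Ccnd1, Myc, Ctnnb1, Cd44, Ptgs2, Odc1, Actb and Gapdh. Ctnnb1 and Gapdh had no tested probe set that named them alone. From the genes so selected, the text favours those that stayed called under most alternatives, a choice made after their values were seen.

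The tests were tested on simulated data with the same design, with 200 of 6118 probe sets changed in each of 5 simulations. Of 2-fold and 4-fold changes they found 29.8% and 66.0% for butyrate against untreated (6.1% false calls), 28.4% and 66.8% for aspirin (7.2% false) and 39.4% and 72.2% for butyrate against aspirin (4.3% false). Of slopes reaching 4-fold and 8-fold they found 52.0% and 67.4% with butyrate (5.4% false), 52.6% and 70.0% with aspirin (4.8% false) and 32.6% and 47.4% for the difference (4.8% false). Since part of the simulated changes was missed, a change missing from the calls is not shown to be absent. In simulations for butyrate with the cell cycle list shifted, camera called that list in 20 of 20 and another list in 1 of 560 cases. The simulated genes varied independently of each other, so these counts do not give the rate of false list calls among correlated genes.

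Alternatives were quantile normalization, scaling of each array to a common median, the floors above, no filter and a filter at the 50th percentile, eBayes without trend, each array left out, time as a factor, only the treatments compared, only the 2 and 24 h arrays with time as a block, only treated arrays from 12 h on, a 2-fold threshold, an adjusted p of 0.01, no time block, all 12 arrays, hours on a linear scale, no 2 h arrays, and the mean of a gene's probe sets in the list tests. The array medians, 133.3 to 200.4, lie not far above the floor, so median centring rests on dim values. After seeing the data, 3 more were added: without untreated 2 h and aspirin 2 h, without the 2 h arrays of all treatments, and without the 52 probe sets at the floor on all 10 treated arrays. Those constant probe sets lower the estimated prior degrees of freedom. Both counts had been seen by then, so the fit as planned was kept. The splits within each hour, the rises without the untreated 24 h array, the simulation of calls shared through the untreated arrays and the look at every probe set of a named gene were also added after seeing the data.

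The calculations used R 4.3.3 and limma 3.58.1. Percentiles of list medians between single arrays came from 10000 random lists.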

Results

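The rat colon carcinoma line CC531 was profiled on 12 expression arrays, each of 1 RNA sample. Cells were left untreated (2 and 24 h), or treated with 4.5 mM butyrate or 3 mM aspirin for 2, 6, 12, 16 and 24 h. Butyrate is a short-chain fatty acid that gut bacteria make from fibre and an inhibitor of histone deacetylases. Aspirin inhibits the cyclooxygenases that make prostaglandins. There were 2 untreated, 5 butyrate and 5 aspirin arrays, with 1 array for each treatment and time. Of 8740 probe sets, 6118 were bright enough to be tested, and they covered 3647 genes. Nothing in the labels says that the arrays come from separate cultures, so the p-values measure only the spread between these arrays. In the comparisons with untreated that spread holds changes over the hours of a treatment as well as array noise, which may be technical. Between the drugs it holds shifts of their difference over the hours, and for slopes departures from a straight line, again with array noise.

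More probe sets differed from untreated cells the longer butyrate acted. Against the mean of both untreated arrays, 689 probe sets differed at least 2-fold after 2 h of butyrate (402 higher, 287 lower) and 1043 after 6 h (697 and 346). The count was 1348 after 12 h (890 and 458), 1441 after 16 h (874 and 567) and 1575 after 24 h (966 and 609). Aspirin gave 637 (199 and 438), 617 (159 and 458), 494 (199 and 295), 546 (306 and 240) and 857 (488 and 369) at the same times. Against the untreated array of the same hour alone, butyrate differed at 991 probe sets at 2 h, where the balance turned (454 higher, 537 lower), and at 1740 at 24 h (1129 and 611). Aspirin then differed at 1105 at 2 h (335 and 770) and at fewer, 811, at 24 h (504 and 307). These counts carry no test and include array noise. The untreated arrays at 24 and 2 h differed 2-fold at 1011 probe sets (346 higher, 665 lower), or 16.5%. Correlations of log2 values lay between 0.866 and 0.945 for untreated with butyrate arrays and at 0.940 for the untreated pair. With the aspirin arrays untreated 2 h correlated at 0.918 to 0.942 and untreated 24 h at 0.952 to 0.97. Each treated array correlated less with untreated 2 h than with untreated 24 h, so the differences from untreated 2 h rest on the more distant control.

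**Figure D1:**
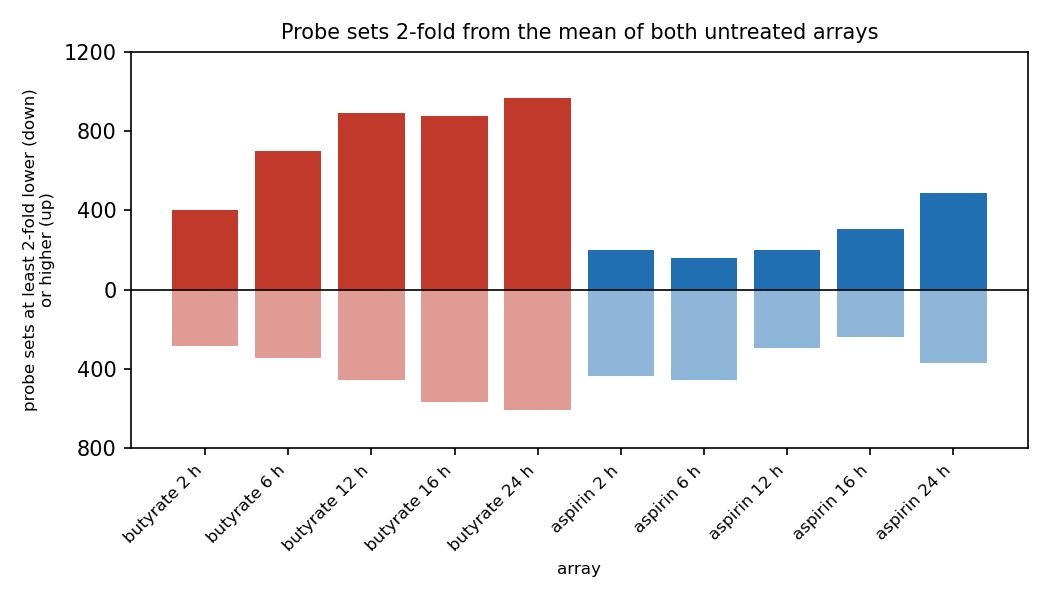
Number of probe sets (y axis) at least 2-fold higher (upward bars) or lower (downward, paler bars) than the mean of both untreated arrays on each treated array (x axis, hours), butyrate in red and aspirin in blue, 1 array per bar. With butyrate the total grew from 689 at 2 h to 1575 at 24 h, and with aspirin it lay between 494 and 857, while against the untreated array of the same hour alone, at 2 and 24 h, it was 991 (454 higher, 537 lower) and 1740 with butyrate and 1105 and 811 with aspirin.

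Butyrate against untreated cells asked which genes the fatty acid changed over its 5 times. Myc, the transcription factor that drives growth and division, fell by 3.94 ± 0.52 on the log2 scale on one probe set (mean ± SE, adjusted p = 0.000644) and by 2.77 ± 0.33 on another (0.000407). Its partner Max rose by at least 2.57 ± 0.39 (0.00187) on 1 of its 2 probe sets, while the other read 0.67 (0.215). Follistatin, Fst, a secreted binder of activin, fell by 5.17 ± 0.65 (0.000612), and the cell-cycle starter cyclin D1, Ccnd1, fell on 3 of its 5 probe sets, by 1.78 ± 0.36 (0.00884) on one. Ccnd3, for cyclin D3, rose on 3 of its 4 probe sets, by 1.08 ± 0.18 (0.00338) on one, while the other read −0.83 (0.561). The prion protein gene Prnp rose by 4.79 ± 0.56 (0.000351). Tissue plasminogen activator, Plat, rose by at least 3.50 ± 0.51 (0.00154), and Gch1, the first enzyme of tetrahydrobiopterin synthesis, rose on 2 of its 3 probe sets, by at least 3.19 ± 0.53 (0.00312) on one.

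Further rises with butyrate were those of Slc27a1, a fatty acid transporter (at least 4.35 ± 0.62, adjusted p = 0.00128), the prostaglandin reductase Ptgr1 (at least 3.43 ± 0.51, 0.00165) and C5h1orf210 (3.63 ± 0.40, 0.000305). The small GTPase gene Rhob rose by 2.20 ± 0.24 (0.000305), the immediate-early factor Egr1 by 2.21 ± 0.22 (0.000291, called on 3 of its 4 probe sets) and the lipid regulator Srebf1 by at least 1.98 ± 0.28 (0.00121). The phosphatase gene Ptpn1 rose by 1.32 ± 0.19 (0.00121), although 1 of its 5 probe sets read −0.03 (0.974), and the protein disulfide isomerase gene P4hb by 1.11 ± 0.19 (0.00343, called on 2 of its 3 probe sets). The G protein subunit gene Gna15 (−2.74 ± 0.46, 0.00311) and Kctd15 (by at least 2.52 ± 0.28, 0.000305, with 4 of 5 butyrate arrays at the floor) fell. The kinase inhibitor gene Cdkn1a (1.65, 0.117, with butyrate 2 h and both untreated arrays at the floor, and 0.12, 0.811, on its other probe set), the adhesion receptor Cd44 (0.47, 0.559) and the polyamine enzyme Odc1 (1.14, 0.148) did not pass the test. Ptgs2, for cyclooxygenase-2, fell on 1 of its 2 probe sets (−1.25, 0.0141, but up to 0.126 without untreated 2 h), while the other read −0.24 (0.755). The actin control Actb fell by 0.35 ± 0.09 (0.0292). That call was lost with quantile normalization, with median centring and without the variance trend, and its change ran from −0.49 to −0.16 over all alternatives.

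In all, 716 of 6118 probe sets changed with butyrate at an adjusted p of 0.05 (limma, 12 arrays): 476 rose, covering 332 genes, and 240 fell, covering 159 genes. On 584 of them the change was at least 2-fold, and on 676 every butyrate array lay on the same side of both untreated arrays. Without any adjustment 1763 had a p under 0.05, where 305.9 were expected by chance. All butyrate arrays lay outside the untreated pair in the same direction on 1703 probe sets, or 27.8%, where independent, exchangeable arrays would give 9.52%. Arrays of a time series are not independent and values tie at the floor, so this is not the share expected without a drug effect. Without the untreated 2 h or the untreated 24 h array most of the 716 were not called, and part of the calls then made were of other probe sets. The count was 1166 without butyrate 2 h, and 344, 310 and 400 without butyrate 12, 16 and 24 h. With time as a factor 317 were called, and 0 on the 2 and 24 h arrays alone with time as a block (577 at an unadjusted p under 0.05). The called probe sets given above with an error were called whichever single array was left out, except those of Ccnd1 (up to 0.0892 without an untreated array) and Actb (up to 0.0725). Other called probe sets of these genes were lost without an untreated array: 1 of Egr1 (0.0549), 1 of P4hb (0.0611), 2 of Ptpn1 (up to 0.112), 2 of Ccnd1 (up to 0.175) and 1 of Ccnd3 (up to 0.255). For Ccnd3 and 1 of Ccnd1 that was also so without butyrate 16 or 24 h.

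**Figure D2:**
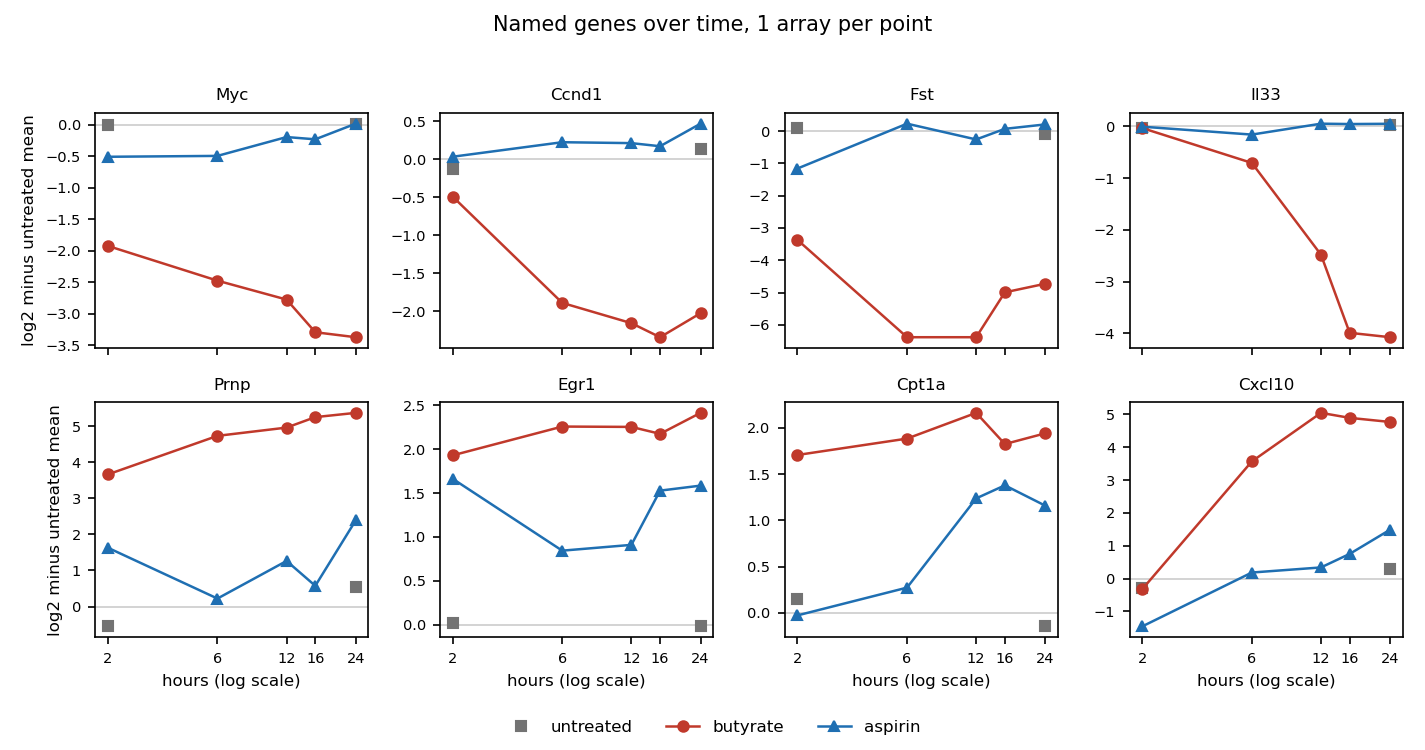
Log2 expression minus the mean of both untreated arrays (y axis) against hours on a log scale (x axis) for 8 genes, with untreated arrays as gray squares, butyrate as red circles and aspirin as blue triangles, 1 array per point. With butyrate, Myc stood at −1.93 and Ccnd1 at −0.49 at 2 h, and Il33 went from −0.03 at 2 h to −4.07 at 24 h.

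Among the gene lists fixed before the data were examined, the genes of cell cycle and DNA replication were lower with butyrate. Of 34 measured, 5 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of −0.87 and an adjusted p of 9.29e-06 against all other genes (camera, and adjusted p = 0.548 with an estimated correlation). They included Tyms, for thymidylate synthase (a fall of at least 1.83, adjusted p = 0.008), and Ccnb1, for mitotic cyclin B1 (−1.78, 0.0287). Genes that build ribosomes, translation factors and polyamine enzymes were lower too: 7 of 23 fell and 1 rose (11 and 1 over the list alone), with a median of −0.79 (0.000277, and adjusted p = 0.548 with an estimated correlation) and Dkc1, a pseudouridine synthase gene, at −2.03. Fatty acid and ketone body oxidation was higher, with 10 of 29 up and 0 down (13 and 1 over the list alone) and a median of 0.55 (9.34e-06, and adjusted p = 0.548 with an estimated correlation). Its members Cpt1a (1.90 ± 0.34, 0.00442) and Cpt2 (1.69 ± 0.28, 0.00311), the carnitine palmitoyltransferases, and Acadm (at least 2.20) and Acadvl (1.87), acyl-CoA dehydrogenases, rose.

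Some of these members depended on an untreated array. Without the 24 h one Cpt1a missed the threshold narrowly (0.0501). Without the 2 h one Tyms (0.0513), Acadm (0.0875) and Acadvl (0.123) missed it. Dkc1 was lost without either untreated array (adjusted p up to 0.0982), and Ccnb1 without either or without butyrate 12 h, butyrate 16 h or aspirin 16 h (up to 0.202). Their other probe sets fell too (−1.38, 0.0209, for Dkc1 and −1.76, 0.0411, for Ccnb1) but were lost in more such fits.

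Genes of the lysosome and membrane traffic were higher with butyrate, with 5 up and 1 down of 30 (11 and 1 over the list alone) and a median of 0.38 (adjusted p = 0.00769, and adjusted p = 0.548 with an estimated correlation). Those of antigen presentation and the interferon response were higher as well, with 6 up and 0 down of 25 (7 and 1 over the list alone) and a median of 0.46 (0.00769, and adjusted p = 0.548 with an estimated correlation). They reached only 0.274 without the untreated 2 h array (median 0.37). Histones and chromatin regulators were lower, with 1 up and 1 down of 15 (2 and 6 over the list alone) and a median of −0.76 (0.0194, and adjusted p = 0.548 with an estimated correlation). So were heat shock genes and chaperones, with 1 up and 3 down of 16 (1 and 8 over the list alone) and a median of −0.55 (0.0233, and adjusted p = 0.548 with an estimated correlation). Their member Hspb1 went the other way, by 3.04 (limma, 0.00903), 2.24 (0.004) and 1.31 (0.0388), with −0.43 (0.42) on another probe set. Hspa9 (−1.26, 0.0318), Dnaja1 (−1.15, 0.0494) and Dnaja2 (−0.75, 0.0495) fell, though another Dnaja1 probe set read 0.36 (0.709). The proteasome had a median of −0.25 with 0 of 25 called (0.0385, and adjusted p = 0.548 with an estimated correlation). Ribosomal proteins had 0 of 36 called and a median of −0.17, but 0.01 with quantile normalization (0.00892, and adjusted p = 0.816 with an estimated correlation). Oxidative phosphorylation had 1 of 26 down and a median of −0.11 (0.039, and adjusted p = 0.572 with an estimated correlation).

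Quantile normalization ended 5 of these calls. The medians of histones (−0.72, adjusted p = 0.0618) and heat shock (−0.56, 0.166) hardly moved, those of the proteasome (−0.16, 0.387) and oxidative phosphorylation (−0.07, 0.627) shrank, and that of ribosomal proteins vanished (0.01, 0.963). The histone call was also lost with the lower floor (−0.64, 0.0527), and that of heat shock with the mean of all probe sets of a gene (−0.36, 0.0655). Leaving out 1 array ended calls too. The call of histones and chromatin regulators was lost without untreated 2 h (median −0.255) or butyrate 24 h (−0.64, 0.0531). Those of heat shock (−0.40) and ribosomal proteins (−0.12) were lost without untreated 24 h. The proteasome was lost without untreated 24 h (−0.14, 0.671) or butyrate 24 h (−0.22, 0.0531), and oxidative phosphorylation without the same arrays (−0.003, 0.911, and −0.10, 0.0531).

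**Figure D3:**
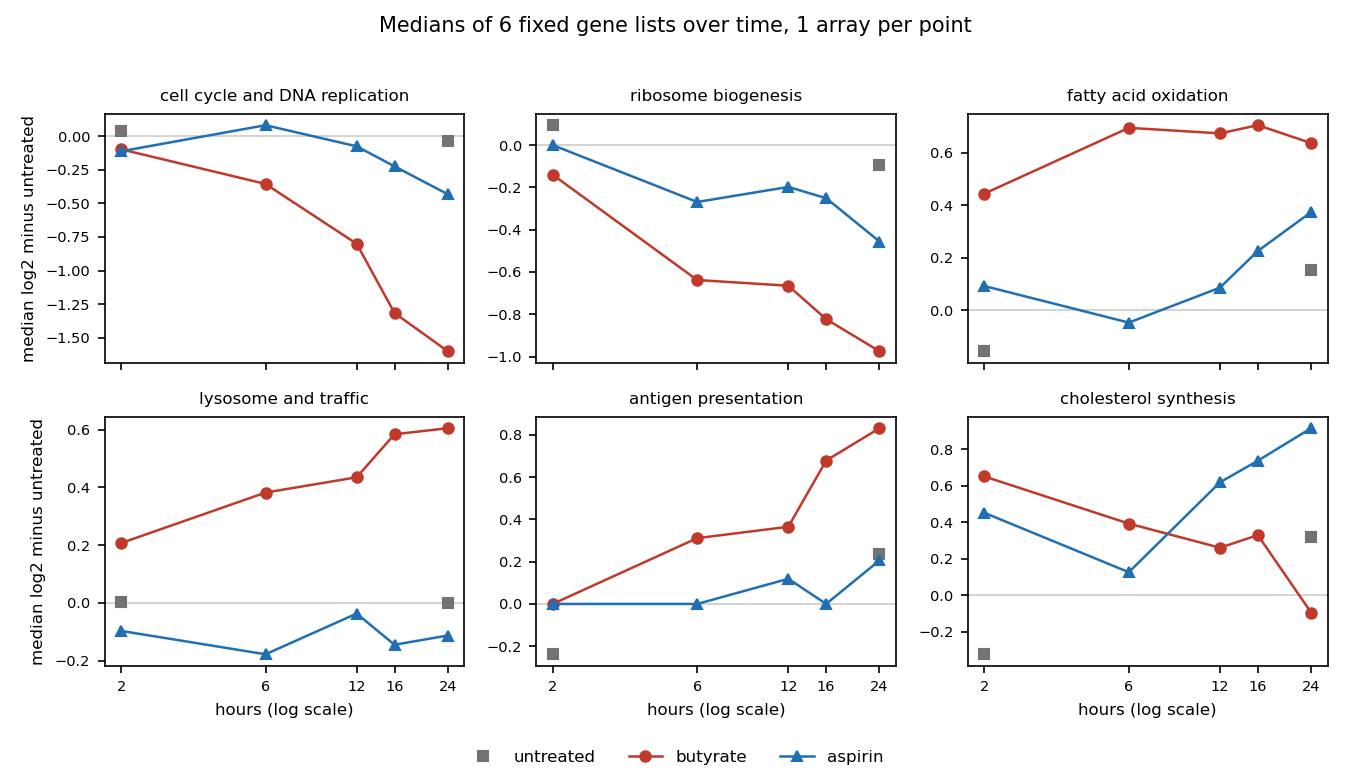
Median log2 difference from the mean of both untreated arrays over the genes of 6 lists (y axis) against hours on a log scale (x axis), with untreated arrays in gray, butyrate in red and aspirin in blue, 1 array per point. With butyrate the cell cycle list went from −0.10 at 2 h to −1.60 at 24 h, and with aspirin cholesterol synthesis reached 0.92 at 24 h while the untreated arrays lay at −0.32 and 0.32.

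The other 19 lists did not pass against all other genes with butyrate. The nearest was that of beta-catenin signalling and targets, with 0 up and 4 down of 27 (1 and 6 over the list alone) and a median of −0.24 (adjusted p = 0.0553). It passed, with a negative median, in 6 alternatives: with the lower floor (0.0386), with the mean of all probe sets (0.0288), and without untreated 24 h (0.0354) or butyrate 2 h (0.0423), 16 h (0.0396) or 24 h (0.0443). Markers of endothelial cells (median −0.27, 0.0911, but 0.0497 without butyrate 16 h), blood and immune cells (−0.09, 0.488), fibroblasts and smooth muscle (−0.19, 0.554) and hepatocytes (−0.09, 0.825) had 0 called genes each. Of intestinal differentiation the keratin genes Krt19 rose, by 0.87 and 1.17 on its 2 probe sets, and Krt18 fell, by 0.48 and 0.84 on its 2 (list median −0.27, 0.192). Krt19 was lost without untreated 2 h (0.187 on the first probe set), and on the second also without untreated 24 h or with median centring (up to 0.107). The first Krt18 probe set was lost with either scaling, and without either untreated array or butyrate 16 h (up to 0.0868), while the second (0.00406) was called with either scaling and whichever array was left out (up to 0.0369). Cholesterol and fatty acid synthesis had 3 up (0.31, 0.351), extracellular matrix 3 up and 2 down (0.22, 0.358) and the amino acid response 1 up and 2 down (0.03, 0.66). Immediate-early factors had 3 up and 3 down (0.25, 0.759). Kinase inhibitors and growth arrest genes had 1 up (0.04, 0.797), apoptosis 3 up (0.00, 0.797) and neuronal genes 2 up and 1 down (0.14, 0.797). Metallothioneins and metal handling had 1 up and 1 down (0.09, 0.797), and growth factor signalling 2 up and 1 down (0.04, 0.797). Glycolysis had 2 up (−0.12, 0.825), NF-kappaB targets 2 up and 1 down (−0.02, 0.825), actin and adhesion 2 up and 4 down (0.01, 0.825) and xenobiotic metabolism 2 up and 1 down (0.07, 0.834).

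With quantile normalization the butyrate medians of the kinase inhibitor (−0.14), apoptosis (−0.14), amino acid (−0.05), metallothionein (−0.01) and growth factor (−0.08) lists turned negative, and with median centring that of actin and adhesion did (−0.13). In the amino acid, growth factor, hepatocyte, glycolysis, NF-kappaB and actin lists the median, the mean and the test did not all share a sign.

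Aspirin against untreated cells asked the same of the cyclooxygenase inhibitor. Few single genes passed. Mog, a myelin glycoprotein gene, fell by at least 1.41 ± 0.17 (adjusted p = 0.00663, with 4 of 5 aspirin arrays at the floor), the immune checkpoint gene Ctla4 by at least 1.34 ± 0.20 (0.0293, 3 of 5 at the floor) and the calcium channel gene Cacna1b by at least 0.99 ± 0.15 (0.0293). The other probe sets of Ctla4 (−0.85, 0.404) and Cacna1b (−0.76, 0.411) did not pass. Egr1 rose by 1.31 ± 0.22, Dgcr6 by at least 1.71 ± 0.29, Ndufv3, of respiratory complex I, by 1.32 ± 0.22, and the cyclophilin gene Ppib by 0.82 ± 0.14 (all 0.036). These rises stood on 1 probe set each, the only one tested for Dgcr6, while the others read 1.11 (0.36), 0.28 (0.844) and 0.15 (0.989) for Egr1, 0.38 (0.839) for Ndufv3 and 0.11 (0.836) for Ppib. Ptgs2, which encodes an aspirin target (−0.24, 0.896, and −0.57, 0.49 on the other probe set), Myc (−0.28, 0.832), Ccnd1 (0.22, 0.885), Cdkn1a (1.06, 0.599, with 2 of 5 aspirin and both untreated arrays at the floor), Cd44 (0.30, 0.874), Odc1 (−0.15, 0.971) and Actb (−0.19, 0.485) did not pass. Nor did the largest other changes that went the same way on every aspirin array, those of Ptgr1 (at least 2.15, 0.249), Aopep (at least 1.75, 0.411), Adam10 (−2.08, 0.234), Myo1c (−2.01, 0.256) and Pdlim5 (−1.94, 0.256). The other probe sets read 0.25 (0.896) for Aopep and −1.29 (0.523) for Pdlim5.

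The enzymes of cholesterol and fatty acid synthesis were higher as a group with aspirin: 17 of 20 had a positive change, with a median of 0.59 and an adjusted p of 2.6e-05 against all other genes (camera). With an estimated correlation the adjusted p = 0.583, and 0 members passed alone, also over the list alone (median 0.28, 0.0926, for the list without untreated 2 h). The untreated 24 h array itself stood 0.65 above the untreated 2 h array for this list. At the same hour the list was 0.78 higher with aspirin than without at 2 h and 0.53 higher at 24 h, on 1 array each and without a test. Fatty acid oxidation was higher, with 0 of 29 called (1 over the list alone) and a median of 0.22 (0.0149, and adjusted p = 0.735 with an estimated correlation). Intestinal differentiation (0 of 29, median −0.24, 0.031) and endothelial markers (0 of 8, median −0.45, 0.0257) were lower, both with adjusted p = 0.583 with an estimated correlation.

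The calls of the aspirin lists were lost without single arrays, in part with medians as large as before. Fatty acid oxidation was lost without untreated 2 h (median 0.12, 0.737) or aspirin 24 h (0.19, 0.0546), and intestinal differentiation without untreated 24 h (−0.28, 0.349) or aspirin 2 h (−0.23, 0.0535). The aspirin 2 h array had an actin 3' to 5' ratio, a sign of RNA integrity, of 1.55, against 0.96 to 1.23 on the others. Its Gapdh ratio, 1.10, was the lowest of the aspirin arrays, so these ratios do not point the same way. Endothelial markers were lost without untreated 2 h (median −0.31, 0.0926), untreated 24 h (−0.65, 0.128), aspirin 2 h (−0.42, 0.0535) or aspirin 6 h (−0.42, 0.0753). With the lower floor fatty acid oxidation (0.21, 0.0658), intestinal differentiation (−0.30, 0.0852) and endothelial markers (−0.56, 0.0852) were lost, and endothelial markers also with the mean of all probe sets (−0.43, 0.0564). Of the lists not called, oxidative phosphorylation passed without untreated 24 h (median 0.25, 0.000714) or with median centring (0.30, 0.0489) and antigen presentation without untreated 24 h (0.19, 0.0381). Ribosomal proteins passed without aspirin 12 h (0.12, 0.0494) and ribosome biogenesis with the mean of all probe sets (−0.34, 0.0185). In the immediate-early, proteasome, neuronal, beta-catenin and metallothionein lists the median, mean and test differed in sign.

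In all, 9 probe sets changed with aspirin (limma, 5 rose and 4 fell, of 4 and 3 genes), 7 of them at least 2-fold and each of them in the same direction on every aspirin array. At an unadjusted p under 0.05 there were 656, against 305.9 expected. On 709 probe sets, or 11.6%, every aspirin array lay outside the untreated pair on one side, where independent, exchangeable arrays would give 9.52%. The count was 45 without untreated 2 h (3 rose and 42 fell), 306 without untreated 24 h (78 rose and 228 fell), 1 without aspirin 12 or 16 h, 5 without aspirin 2 or 24 h, and 4 without butyrate 6, 12, 16 or 24 h. It was 0 with quantile normalization (limma, 628 at an unadjusted p under 0.05), 0 with time as a factor (615) and 0 on the 2 and 24 h arrays alone with time as a block (293). Of the named genes Mog, largely at the floor with aspirin, was alone called whichever array was left out (adjusted p up to 0.0238). Ctla4 and Cacna1b were lost without aspirin 12 or 16 h and the 4 rises each in at least 9 of 12 such fits.

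The responses to both drugs were also compared with each other, since their changes share the same untreated arrays. One Egr1 probe set, at 2.21 with butyrate and 1.31 with aspirin, was among 5 that rose with both drugs, while 4 fell with both and 0 went opposite ways. Independent lists would share 0.389 rises and 0.157 falls. That figure leaves out the shared controls: in simulations without any drug effect, the 716 and 9 probe sets with the smallest p shared 8.17 in the same direction on average, so the overlap of all 9 is no evidence of a common response. Over 6118 probe sets the changes correlated at r = 0.451 (Spearman 0.430) and 61.5% had the same sign. Simulated arrays without any drug effect gave a mean r of 0.715 (Spearman 0.678) and 75.4% from the shared controls alone, so the correlation gave no sign of a common response by itself. The covariance was 0.162 against a simulated mean of 0.110 (100 simulations), an excess of 0.053. Part of that excess may come from the shared controls, since it was 0.00151 without the untreated 2 h array and 0.1997 without the untreated 24 h array.

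Butyrate against aspirin, matched by time and free of the untreated arrays, asked where the drugs differed. Lower with butyrate were Fst (−4.99 ± 0.63, adjusted p = 0.00756), Myc (−2.48 ± 0.31, 0.00756, with −3.62 on the other probe set), Kctd15 (by at least 2.68 ± 0.20, 0.00461) and Gnl3, for a nucleolar GTPase (−1.60 ± 0.18), though another probe set of Gnl3 read 0.12 (0.467). Higher with butyrate were Prnp (3.58 ± 0.41, 0.00637), Plat (3.21 ± 0.33, 0.0056), Glul, for glutamine synthetase (3.18 ± 0.21, 0.00461, with 1.53 to 1.60 on the other 3 probe sets), and the amyloid precursor-like gene Aplp2 (2.90 ± 0.23, 0.00461). The clock gene Bmal1 (at least 2.88), Sord, for sorbitol dehydrogenase (at least 2.88), and Gch1 (2.79, called on 2 of its 3 probe sets) with its regulator Gchfr (2.91) were higher as well. So were the adhesion molecule Icam1 (at least 2.13 ± 0.22), Rhob (1.91 ± 0.18), the sheddase Adam10 (1.86 ± 0.16) and the long-chain acyl-CoA synthetase Acsl3 (1.29 ± 0.16, 0.00722). Ccnd1 was lower (−2.00 ± 0.31, 0.011, called on 4 of its 5 probe sets), while Cdkn1a (0.59, 0.218), Cd44 (0.17, with 1.18, 0.0587, and 1.02, 0.0657, on its other probe sets) and Actb (−0.16, 0.117) did not pass. Actb was called with median centring (−0.47) and stood at 0.07 with quantile normalization. On 1 of 2 probe sets each, Odc1 was higher (0.92, 0.0279, with 1.28 and 0.0786 on the other) and Ptgs2 lower (−0.68, 0.0258, with 0.00 on the other). Both of these calls were lost without the 6, 12, 16 or 24 h array of either drug, and that of Odc1 also with median centring (adjusted p up to 0.102 for Odc1 and 0.0853 for Ptgs2).

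Between the drugs, cell cycle genes were lower with butyrate, with 15 down and 2 up of 34 (16 and 2 over the list alone) and a median of −0.59 (adjusted p = 6.4e-06, and adjusted p = 0.622 with an estimated correlation). Ribosome biogenesis was lower too, with 8 down and 2 up of 23, as over the list alone, and a median of −0.36 (0.000663, and adjusted p = 0.247 with an estimated correlation). The lysosome list was higher, with 16 up and 1 down of 30 (19 and 1 over the list alone) and a median of 0.47 (0.000223, and adjusted p = 0.247 with an estimated correlation). Lysosome members that rose were the coat adaptors Ap1b1 (2.49 ± 0.19, 0.00461) and Ap2a2 (2.01 ± 0.20) and the proton pump subunit Atp6v1b2 (1.38). Fatty acid oxidation was higher, with 11 up and 1 down of 29 (16 and 2 over the list alone) and a median of 0.52 (0.00555, and adjusted p = 0.641 with an estimated correlation). The extracellular matrix was higher, with 9 up and 2 down of 38 (14 and 3 over the list alone) and a median of 0.39 (0.0484, and adjusted p = 0.622 with an estimated correlation). Its member biglycan, Bgn, was higher by at least 2.36, while another of its probe sets read −0.08 (0.885).

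The large housekeeping families were slightly lower with butyrate than with aspirin as deposited. Ribosomal proteins had 13 down and 0 up of 36 (23 and 0 over the list alone) and a median of −0.23 (adjusted p = 6.4e-06, and adjusted p = 0.622 with an estimated correlation). Oxidative phosphorylation had 9 down and 0 up of 26 (13 and 0 over the list alone) and a median of −0.31 (4.81e-05, and adjusted p = 0.201 with an estimated correlation). The proteasome had 8 down and 0 up of 25 (10 and 0 over the list alone) and a median of −0.25 (0.000328, and adjusted p = 0.254 with an estimated correlation). Heat shock genes and chaperones had 4 down and 1 up of 16, as over the list alone, and a median of −0.51 (0.0362, and adjusted p = 0.622 with an estimated correlation). Hspb1 of this list was higher with butyrate (1.95, 1.57 and 1.09, limma adjusted p up to 0.00821), with 0.21 (0.614) on another probe set. With quantile normalization the median of ribosomal proteins vanished (−0.01, 0.879) and those of oxidative phosphorylation (−0.20, 0.109) and the proteasome (−0.155, 0.109) shrank. The calls of ribosome biogenesis (median −0.405, 0.0746) and heat shock genes (−0.45, 0.365) were lost too, but their medians hardly moved. Heat shock was also lost with median centring (−0.82, 0.0616), the lower floor (−0.47, 0.0504) and the mean of all probe sets (−0.19, 0.272). The extracellular matrix was lost with median centring (0.10, 0.06), the higher floor (0.16, 0.298), the lower floor (0.42, 0.115) and the filter at the 50th percentile (0.40, 0.237). Without the 12 or 24 h array of either drug the extracellular matrix (0.29, 0.0699, and 0.34, 0.0792) and heat shock (−0.37, 0.0569, and −0.40, 0.0792) lists were lost. Antigen presentation had a median of 0.48 and an adjusted p of 0.082, but passed without the 2 or 12 h array of either drug (0.0404 and 0.0382). Other uncalled lists that passed were cholesterol synthesis without the 2 h (−0.29, 0.0429) or 6 h array of either drug (−0.45, 0.0486) and with the filter at the 50th percentile (−0.33, 0.0414), histones without the 2 h array of either drug (−0.29, 0.0172) and with the mean of all probe sets (−0.15, 0.0324), and actin with quantile normalization (0.33, 0.0479). In the kinase inhibitor, apoptosis, xenobiotic, amino acid, NF-kappaB, fibroblast and blood cell lists the median, mean and test differed in sign.

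In all, 1540 probe sets differed between the drugs (limma, 10 arrays): 952 were higher with butyrate, of 658 genes, and 588 lower, of 367 genes. On 701 the difference was at least 2-fold and 2479 had an unadjusted p under 0.05. On 2012, or 32.9%, the sign was the same at all 5 times, where independent differences centred on 0 would give 6.25%. The hours of a drug are not independent and the centre moves with the scaling, so this is not the share expected without a drug effect. The balance of directions depended on the scaling. The median of all probe sets was 0.10 as deposited, −0.04 with quantile normalization and −0.12 with median centring, and the share higher with butyrate was 61.8%, 52.0% and 32.6%. For aspirin against untreated, median centring moved that median from −0.04 to 0.07. Without single arrays the count fell to 442, 362, 241 and 594 (butyrate 6, 12, 16 and 24 h) or to 461, 340, 244 and 607 (aspirin at the same times), where each such fit also loses its partner of that hour. Of the probe sets given with an error for this comparison, that of Fst was lost without butyrate or aspirin 16 h (0.0516), that of Ccnd1 in 8 of 10 such fits (adjusted p up to 0.0602), and the others in none. Of the other called probe sets, that of Fst (−3.34) was lost in none, while 3 of Ccnd1 (up to 0.0748), 2 of Glul (up to 0.0535), 1 of Icam1 (up to 0.0816) and 1 each of Aplp2, Gnl3, Myc and Ap1b1 (up to 0.0576) were lost in some.

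The slope over log2 hours asked which genes kept changing during butyrate. Il33, for an alarmin cytokine, fell by 1.24 ± 0.16 per doubling of time (adjusted p = 0.00413) and the calmodulin-like gene Calml4 by 1.04 ± 0.11 (0.00189). The adhesion gene Ceacam4 rose by at least 1.29 ± 0.08 (0.000987) and Gstm1, for a detoxifying glutathione transferase, by 1.44 ± 0.11 (0.00141). The chemokine gene Cxcl10 rose by 1.5 ± 0.22 (0.00833), Map4k1 by at least 1.67 ± 0.18 (0.0022) and the microtubule gene Mapt by at least 1.30 (0.00483). At butyrate 2 h Ceacam4, Map4k1 and Mapt were at the floor and Gstm1 was at 6.53, just above it, so the sizes of these slopes depend on the floor. Falls were those of Myc (−0.42, 0.00549), Pcsk6 (−1.23, 0.00141), the replication helicase gene Mcm5 (−1.09, 0.0246), the serine synthesis gene Psat1 (−0.98, 0.0108) and Ccnd1 (−0.47, 0.0206). Ccnd1 was called on 3 of 5, Psat1 on 2 of 3 and Pcsk6 on 1 of 2 probe sets. Without butyrate 2 h the adjusted p was 0.282 for Cxcl10, 0.0653 for Map4k1 and Pcsk6, 0.221 for Mapt, 0.0861 for Myc and 0.757 for Ccnd1. Ccnd1 was also lost without butyrate 16 h, Psat1 without butyrate 2 or 24 h (up to 0.0947) and Mcm5 without butyrate 2, 16 or 24 h (up to 0.12). Ceacam4, Il33, Calml4 and 2 of the 3 Gstm1 probe sets were called whichever array was left out, as was 1 other probe set each of Map4k1 (1.09), Mapt (at least 1.045) and Psat1 (−0.91). Without butyrate 2 h the third probe set of Gstm1 (0.0897) and the other called ones of Mapt (0.0517), Myc (up to 0.784) and Ccnd1 were lost. Odc1 rose with time on both probe sets (0.65, 0.0206, and 0.44, 0.0167), but not with median centring or without butyrate 2, 16 or 24 h (adjusted p up to 0.276). Cdkn1a (0.53, 0.281), Cd44 (0.23, 0.24), Ptgs2 (0.24, 0.471) and Actb (−0.03, 0.623) did not pass.

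Cell cycle genes fell with time in butyrate, 17 of 34 with 0 up (23 and 0 over the list alone), with a median slope of −0.40 (adjusted p = 1.55e-15, and adjusted p = 0.141 with an estimated correlation). Their median difference from untreated went from −0.10 at 2 h to −1.60 at 24 h. Ribosome biogenesis fell as well, with 8 down and 1 up of 23 (9 and 1 over the list alone) and a median of −0.20 (1.62e-05). It was the 1 list in all 6 comparisons that also passed with an estimated correlation (adjusted p = 0.049), though not without butyrate 2 h (median −0.09, 0.0595). Cholesterol synthesis fell, with 3 of 20 down (6 over the list alone) and a median of −0.17 (9.31e-05, and adjusted p = 0.204 with an estimated correlation). Histones and chromatin regulators fell as a list, with 5 of 15 down, as over the list alone, and a median of −0.21 (9.62e-05, and adjusted p = 0.122 with an estimated correlation). The amino acid response had 4 of 23 down (6 down and 1 up over the list alone) and a median of −0.12 (0.000758, and adjusted p = 0.159 with an estimated correlation). Heat shock genes had 4 down and 2 up of 16 (8 and 2 over the list alone) and a median of −0.15 (0.007, and adjusted p = 0.204 with an estimated correlation). Without drug, histones and chromatin regulators also fell, by 0.47 from 2 to 24 h over the whole span (1 array each). Their fall therefore cannot be credited to butyrate alone. The other medians moved by −0.07 (cell cycle), −0.19 (ribosome biogenesis), 0.65 (cholesterol), −0.08 (amino acid) and 0.08 (heat shock) without drug.

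Other lists climbed over the butyrate series. Neuronal genes had 6 of 27 up, as over the list alone, and a median of 0.14 (adjusted p = 0.000787, and adjusted p = 0.0794 with an estimated correlation). Kinase inhibitors had 2 of 14 up (3 over the list alone) and a median of 0.22 (0.0135, and adjusted p = 0.198 with an estimated correlation). Antigen presentation had 5 up and 1 down of 25 (6 and 1 over the list alone) and a median of 0.20 (0.0313), and the lysosome 2 of 30 up (6 up and 1 down over the list alone) and a median of 0.11 (0.0423). For both the adjusted p = 0.156 with an estimated correlation. Without drug, antigen presentation also rose, by 0.48 from 2 to 24 h over the whole span (1 array each). Its climb therefore cannot be credited to butyrate alone. The neuronal (0), kinase inhibitor (0.02) and lysosome (−0.004) medians hardly moved without drug. Without butyrate 2 h kinase inhibitors (median 0.18), antigen presentation (0.095) and the lysosome (0.13) reached 0.0628. The lysosome was also lost without butyrate 6 h (0.10, 0.0699), 16 h (0.09, 0.0687) or 24 h (0.11, 0.0632), with median centring (0.002, 0.284) and with the lower floor (0.105, 0.0573). Antigen presentation was also lost with the higher floor (median 0.12, 0.057) and the filter at the 50th percentile (0.23, 0.0673). Of the lists not called, oxidative phosphorylation passed, with a negative median, in 5 alternatives (−0.165, 0.00258, with median centring) and ribosomal proteins with median centring (−0.125, 0.00107) or without butyrate 24 h (−0.04, 0.036). In the beta-catenin, apoptosis, intestinal, glycolysis and metallothionein lists the median, mean and test differed in sign.

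In all, 550 probe sets had a slope with butyrate (limma, 293 up and 257 down, of 222 and 189 genes), and 1472 had an unadjusted p under 0.05. Of those called 53.3% rose, against 24.6% with median centring. The count was 81 without butyrate 2 h, 231 without 16 h and 257 without 24 h.

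With aspirin the slopes asked the same question. Rising genes included Itgb7, for an integrin of lymphocyte homing (0.91 ± 0.12 per doubling, adjusted p = 0.02), the transcription factor gene Cebpb (0.91 ± 0.13, 0.0215) and the ectonucleotidase gene Entpd2 (0.83 ± 0.08, 0.0154). Urokinase, Plau, rose by 0.83 ± 0.11 (0.02), and Hsd11b1, whose enzyme regenerates active glucocorticoid, by 0.80 ± 0.09 (0.0168). The mitochondrial genes Higd1a (−0.71, 0.0228, at the floor on 3 of 5 aspirin arrays) and Timm10b (−0.51) fell, as did Rchy1 (−0.51), Akap8 (−0.46) and Ylpm1 (−0.45). Itgb7, Higd1a and Ylpm1 were called on 1 of 2 and Timm10b on 1 of 3 probe sets. The probe sets given for these 10 genes were each lost without at least 1 array. That of Entpd2 and the other of Cebpb (0.57) were lost only without aspirin 24 h (0.0769), and the other of Entpd2 (0.47) in 5 of 10 such fits (up to 0.0866). Cd44 rose on 1 of its 3 probe sets (0.79, 0.0215), with 0.74 (0.0611) and 0.38 (0.104) on the others, and that call was lost without butyrate 6 or 16 h or aspirin 16 or 24 h (up to 0.0822).

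Of the lists, the amino acid response rose over the aspirin series, with 2 of 23 up (5 over the list alone) and a median of 0.14 (adjusted p = 0.0079, and adjusted p = 0.301 with an estimated correlation). NF-kappaB targets had 2 of 25 up (4 over the list alone) and a median of 0.11 (0.0115, and adjusted p = 0.182 with an estimated correlation). Kinase inhibitors had 1 of 14 up (6 up and 1 down over the list alone) and a median of 0.31 (0.0148, and adjusted p = 0.301 with an estimated correlation). Immediate-early factors had 2 of 24 up (3 over the list alone) and a median of 0.13 (0.0172, and adjusted p = 0.43 with an estimated correlation). Cholesterol synthesis had 0 of 20 called (4 up over the list alone) and a median of 0.15 (0.0307, and adjusted p = 0.47 with an estimated correlation). Growth factor signalling had 1 of 51 up (3 over the list alone) and a median of 0.10 (0.0307, and adjusted p = 0.367 with an estimated correlation). Without drug the cholesterol list also rose, by 0.65 from 2 to 24 h over the whole span (1 array each). Its rise therefore cannot be credited to aspirin. The amino acid (−0.08), NF-kappaB (0), kinase inhibitor (0.02), immediate-early (0.05) and growth factor (−0.19) medians showed no such rise without drug.

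Small falls with time in aspirin, with 0 members called, were those of ribosomal proteins (median −0.07, adjusted p = 3.19e-05, and adjusted p = 0.43 with an estimated correlation), ribosome biogenesis (−0.08, 0.00425, and adjusted p = 0.182 with an estimated correlation) and the proteasome (−0.05, 0.0172, and adjusted p = 0.301 with an estimated correlation). Cell cycle genes (−0.08, 0.0172, and adjusted p = 0.524 with an estimated correlation) and oxidative phosphorylation (−0.06, 0.0362, and adjusted p = 0.301 with an estimated correlation) did likewise. Over the list alone ribosome biogenesis had 4 down and the proteasome 1 up and 1 down. Without drug the 5 medians moved by 0.065, −0.19, 0.13, −0.07 and 0.35 from 2 to 24 h, in the same order and on 1 array each. With quantile normalization these 5 lists (medians −0.03, −0.08, −0.03, −0.06 and −0.03, with 0.184, 0.0555, 0.301, 0.202 and 0.535) and growth factor signalling (0.03, 0.112) did not pass, and with the filter at the 50th percentile oxidative phosphorylation did not (−0.055, 0.0644).

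Without aspirin 24 h the adjusted p of the aspirin slope was 0.0628 for NF-kappaB targets, whose median grew to 0.205, 0.158 for cell cycle (−0.04) and immediate-early genes (0.11), and 0.314 for cholesterol synthesis (0.12). It was 0.207 for kinase inhibitors (0.15), 0.378 for growth factor signalling (0.08) and 0.0729 for the proteasome (−0.04). Without aspirin 2 h, the array with the actin ratio of 1.55 but a Gapdh ratio of 1.10, it was 0.78 for ribosomal proteins (median 0.02) and 0.55 for oxidative phosphorylation (0.00), while fatty acid oxidation, not called otherwise, passed (0.215, 0.00122). Without aspirin 16 h it was 0.0588 for cell cycle genes (−0.09), 0.0505 for cholesterol synthesis (0.135) and 0.0571 for oxidative phosphorylation (−0.05). Without aspirin 6 h it was 0.0726 for cholesterol synthesis (0.12) and growth factor signalling (0.09). The antigen presentation, actin, fibroblast and hepatocyte lists had a median, mean and test of differing sign.

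In all, 101 probe sets had a slope with aspirin (limma, 81 up and 20 down, of 60 and 17 genes), and 1204 had an unadjusted p under 0.05. Of those called 80.2% rose, against 59.1% with quantile normalization (81 up and 56 down), 36.6% with median centring (53 and 92) and 66.9% with a higher floor (83 and 41). With the first and last of these more falls were called while the count of rises hardly moved, though not all calls were the same probe sets. The count was 170 (128 up and 42 down) when the probe sets at the floor on all treated arrays were left out, an alternative chosen after seeing the data. It was 6, 55, 16 and 65 without butyrate 6, 12, 16 and 24 h, and 231, 27 and 7 without aspirin 6, 16 and 24 h. Without aspirin 2 h it was 89, of which only 15 were among the 101.

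The difference of the slopes asked which genes moved apart over time. Ceacam4 (1.23 ± 0.11, adjusted p = 0.0108), Gstm1 (1.45 ± 0.16, 0.014), Mapt (1.19 ± 0.15, 0.0202) and Map4k1 (1.39, 0.0428) rose with butyrate. On the aspirin arrays these probe sets were at or near the floor of 6.51: that of Mapt on 5 of 5 arrays and that of Map4k1 on 4 of 5 were at it, and Ceacam4 read at most 6.85 and Gstm1 at most 7.34. The sizes of these 4 differences therefore depend on the floor, and a slope with aspirin could not be measured on this Mapt probe set. Another Mapt probe set was not at the floor on all aspirin arrays, and its difference was 1.16 (0.0586). Relative to aspirin, Cyp51, for a sterol demethylase of cholesterol synthesis (−1.39 ± 0.14, 0.014), Cad, the multienzyme that starts pyrimidine synthesis (−1.31, 0.0374, at the floor on 3 of 5 butyrate and 2 of 5 aspirin arrays), and Il33 (−1.27 ± 0.22, 0.0385) declined. So did Gsr, for glutathione reductase (−1.03, 0.0477), the kinase gene Mapkapk3 (−1.01 ± 0.15, 0.0252) and Myc (−0.56 ± 0.08, 0.0232). Of several probe sets, Gstm1, Mapt and Gsr passed on 2 of 3, Map4k1 and Myc on 1 of 2 and Cyp51 on 2 of 5, 1 of which read 0.23 (0.203). Of these, Ceacam4 was called whichever array was left out (adjusted p up to 0.0416) and the others were each lost without at least 1.

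The amino acid response declined relative to aspirin, with 4 of 23 down (9 over the list alone) and a median of −0.34 (adjusted p = 3.97e-08, and adjusted p = 0.175 with an estimated correlation). The cell cycle list had 1 of 34 down (11 over the list alone) and a median of −0.33 (1.19e-07, and adjusted p = 0.303 with an estimated correlation). Cholesterol synthesis had 2 of 20 down (8 over the list alone) and a median of −0.31 (1.98e-06). Histones and chromatin regulators had 0 of 15 called and a median of −0.21 (0.00535). For both the adjusted p = 0.275 with an estimated correlation. Neuronal genes gained, with 0 of 27 called (3 up over the list alone) and a median of 0.11 (0.0159, and adjusted p = 0.22 with an estimated correlation). Without aspirin 2 h (actin ratio 1.55, Gapdh ratio 1.10) the cell cycle (median −0.10, 0.17), histone (−0.08, 0.462) and neuronal (0.07, 0.184) lists no longer passed. The neuronal list was also lost with the lower floor (0.15, 0.185). Lists not called that passed in some alternatives were beta-catenin (2, median −0.11 and 0.0357 in one), heat shock (3, −0.30 and 0.0199), ribosomal proteins (3, 0.10 and 0.000638) and antigen presentation (1, 0.26 and 0.0112). In the kinase inhibitor, immediate-early, fatty acid oxidation, actin and blood cell lists the median, mean and test had differing signs.

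In all, 106 probe sets differed in slope (limma): the slope with butyrate minus that with aspirin was above 0 on 42, of 31 genes, and below 0 on 64, of 46 genes. An unadjusted p under 0.05 was found on 1113. The count was 29, 50 and 11 without butyrate 2, 12 and 16 h, and 38, 44, 3 and 12 without aspirin 2, 12, 16 and 24 h. It was 0 without the 2 h arrays of both drugs (limma, 992 at an unadjusted p under 0.05).

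Tests within each list, without comparison to other genes, found 3 of 29 lists going one way on balance with butyrate and 24 holding changes in either direction, against 0 and 1 with aspirin. Between the drugs these counts were 10 and 29. For the slopes they were 15 and 28 with butyrate, 15 and 22 with aspirin, and 6 and 21 for their difference. Changes across the whole array also make lists pass the either-direction test, since it does not compare them with other genes. Between the drugs 2479 of 6118 probe sets had an unadjusted p under 0.05 (limma). The second counts are therefore not particular to these lists.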

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

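Of the tests in this part, those of signal and RNA quality on the untreated 2 h array, of the rises without the untreated 24 h array and of the splits within each hour were chosen only after the result was seen. The requirement that the bootstrap interval pass a bound too was added after a first run, and it left open 2 explanations whose value alone met its bound, the floor for the first pattern and time in culture for the third. The bootstrap drew probe sets on the same arrays, so its intervals leave out the spread between arrays and are too narrow in that respect. Values that stood apart from the rest of their group (Dixon, groups of 5) were looked for in array quality (1 of 12 groups), list medians (3 of 58) and named genes (21 of 148, of which 12 at butyrate 2 h, 4 at aspirin 24 h and 2 at aspirin 6 h). At 8 of the 21 genes the other 4 arrays lay at the floor, so that any value above it was picked. The groups are time courses, so an early or late array that stands apart is also a time point. Some values would be picked by chance too, and most of the named genes were chosen for large or steep changes. The counts therefore carry no weight of their own.

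At butyrate 2 h, 42.8% of all values were at the floor (38.8 to 39.9% on the other butyrate arrays), the fatty acid oxidation median was 0.44 (0.64 to 0.70) and the extracellular matrix median 0.00 (0.26 to 0.32). The blood and immune marker median was 0.19 at butyrate 24 h (−0.22 to −0.16). Log2 values at butyrate 2 h, with those of the later butyrate arrays, were 8.38 for Plat (10.16 to 10.61), 8.53 for Gch1 (9.97 to 10.11), 9.77 for Bend3 (7.22 to 7.75), 8.17 for Cxcl10 (12.06 to 13.54), 9.24 for Glul (10.44 to 10.92), 9.31 for Ndrg3 (10.54 to 10.89), 6.51 for Ndrg4 (9.63 to 10.73), 6.51 for Cdkn1a (8.33 to 8.69) and 13.24 for Ccnd1 (11.39 to 11.85). Kctd15 (6.98), Prx (7.85) and Mog (6.90) were above the floor of 6.51 at butyrate 2 h and at it later. Adgrl2 was at 6.51 at butyrate 16 h, just above the floor.

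On the aspirin arrays, C5h1orf210 was at 6.94 at 2 h (8.06 to 8.49 later), and at 24 h Gch1 was at 8.37 (6.51 to 6.81 before), Errfi1 at 9.88, Bmal1 at 7.16 and Map4k1 at 8.04 (all at the floor before). Mog was at 6.70 at 6 h (floor otherwise), Il33 at 13.31 at 6 h (13.46 to 13.52) and Ptgs2 at 6.51 at 12 h (7.67 to 7.98).

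The drugs differed in slope at 106 probe sets, by a test of the difference itself. The differences, butyrate minus aspirin per doubling of time, were 1.39 for Map4k1, 1.45 for Gstm1, 1.23 for Ceacam4, 1.2 for Ndrg4, 1.19 for Mapt, −1.27 for Il33, −0.84 for Pcsk6, −1.0 for Plau, −1.39 for Cyp51, −1.31 for Cad, −1.03 for Gsr, −1.01 for Mapkapk3 and −0.56 for Myc. The probe sets given for Mapt and Ndrg4 were at the floor on 5 of 5 aspirin arrays and that of Map4k1 on 4 of 5. Those of Ceacam4 and Gstm1 were at or near it, and that of Cad was at it on 3 of 5 butyrate arrays. The sizes of these differences therefore depend on the floor. The other probe set of Ndrg4 read 0.59 (0.128) and that of Pcsk6 −0.27. The list medians that differed were −0.33 for cell cycle, −0.21 for histones and chromatin regulators, −0.34 for the amino acid response, −0.31 for cholesterol synthesis and 0.11 for neuronal genes. With an estimated correlation none of these lists passed (adjusted p = 0.303, 0.275, 0.175, 0.275 and 0.22).

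Regrouping asked how often other splits of the 10 treated arrays gave as many probe sets. Among 100 drawn splits, only the real one (1) gave as many between butyrate and aspirin, 1540, and the highest other gave 257, while for the difference of slopes 2 of 100 did, the real one (106) included. Most of these splits break the match by hour that the first fit uses. Only 16 splits keep 1 array of each drug at every hour, so a share under 0.05 could not be reached. Among them the real split alone (1) gave 1540 and the highest other 0 (limma), and for the slopes 2 did, with 106 and 237. The split with 237 exchanges the 2 h arrays of the drugs (butyrate 2 h with aspirin 6, 12, 16 and 24 h). That points to a structure of the samples, since a lasting gap between the drugs turns into a slope once the 2 h arrays are exchanged.

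The first pattern weighed was that more probe sets rose than fell with butyrate, 66.5% of the 716 called. An array-wide scaling or compression effect would bring the share to about 50% once the arrays are given the same distribution, and with quantile normalization it was 58.9% (95% bootstrap interval over probe sets 55.4 to 62.4%, 417 up and 291 down). With median centring it was 68% (346 up and 163 down). Leaving out a single array moved it further than that interval, to 73% without butyrate 12 h. A floor that hides falls of dim probe sets would make the excess vanish among bright ones, and there it was 64.0% (59.7 to 68.4%, 484 probe sets). The untreated 24 h array alone could account for the excess, since without it 47.6% rose (42.9 to 52.2%, 220 up and 242 down), against 68.9% of 357 without the untreated 2 h array. The values for scaling and for the floor do not decide, and that inhibited histone deacetylation may open more genes than it closes stays a hypothesis without a test here.

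The second pattern was that the untreated arrays at 2 and 24 h lay far apart, at 1011 probe sets. Were it time in culture, the aspirin arrays at 24 and 2 h should differ likewise, but their difference at these probe sets was 0.0579 of the untreated one (0 to 0.0954), which argues against it if aspirin cultures age as untreated ones do. Low signal or degraded RNA on the untreated 2 h array would place its quality values outside those of the others, and 0 of 6 lay there. Noise of dim probe sets stays open: among 1928 bright probe sets 8.35% differed 2-fold, within the range of 1.56 to 11.6% over pairs of aspirin arrays, so the untreated pair cannot be told apart from other pairs by that measure. Every treated array, those at 2 h included, correlated less with untreated 2 h than with untreated 24 h. No cause was found, and because of this gap the tests against untreated were repeated without either array.

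The third pattern was that aspirin slopes mostly rose, 80.2% of 101. An array-wide drift over time could account for the share: with quantile normalization it was 59.1% (50.4 to 67.2%), with 81 up and 56 instead of 20 down. Of these 137 calls 84 were among the 101, so the equal count of rises does not show that they are the same probe sets. With median centring the share was 36.6%, with 53 up and 92 down. The aspirin 2 h array alone did not make these slopes, whose median size without it was 0.984 of the full one (0.902 to 1.16), but which probe sets were called did depend on it: only 15 of the 101 were among the 89 called without it. Time in culture without a drug cannot be told apart, because the untreated slope at these probe sets was 0.0488 of the aspirin slope (−0.0749 to 0.229) but rests on only 2 arrays. A continuing response to aspirin stays possible.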

How the results depend on the processing

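Of the alternatives here, those without the untreated 2 h and aspirin 2 h arrays, without the 2 h arrays of all treatments and without the probe sets constant at the floor were added after seeing the data. The labels give no culture or donor by which to pair arrays, so matching was by hour: butyrate and aspirin were compared with time as a block, and the 2 and 24 h arrays with untreated likewise. Low signal limits what can be said of dim genes: a count of 2-fold changes follows the floor by construction. Where no reason is given, the cause was not tested. With 1 untreated array left out, the lone one is assumed to vary like the other groups.

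With butyrate 716 probe sets changed, and 184 at an adjusted p of 0.01, 317 with time as a factor, 306 on the arrays compared alone, 0 on the 2 and 24 h arrays alone (577 at an unadjusted p under 0.05 by limma; 6 arrays), 1284 from 12 h on and 376 without untreated 2 h and aspirin 2 h. With aspirin 9 became 1 at 0.01, 0 with quantile normalization (628 unadjusted), 5 with median centring, 18 and 8 with the higher and lower floor, 0 with the filter at the 50th percentile (479), 5 without trend, 6 on the arrays compared alone, 0 with time as a factor (615), 0 on the 2 and 24 h arrays (293), 4 from 12 h on, 45 without untreated 2 h and aspirin 2 h and 51 without any 2 h array. Of the 6 aspirin calls on the arrays compared alone, only 1 was among the 9. Between the drugs 1540 became 701 with a 2-fold threshold and 296 at 0.01. Without the 2 h arrays 48 butyrate slopes were called in place of 550, and 37 of these were among the 550. The 101 aspirin slopes became 282 with the lower floor, 246 with the filter at the 50th percentile, 230 on linear hours, 23 without the 2 h arrays and 170 without constant probe sets. Of the 23, 5 were among the 101, and of the 230, 60 were. The 106 slope differences became 69 with median centring, 167 with the filter at the 50th percentile, 70 on linear hours and 0 without the 2 h arrays (992).

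Counts of 2-fold differences with the higher and lower floor were 642 and 1597 between the untreated arrays, 409 and 1417 for butyrate 2 h, 1680 (lower) for butyrate 6 h, 354 and 1413, 347 and 1405, 244 and 1252, 304 and 1235, and 546 and 1607 for aspirin 2, 6, 12, 16 and 24 h, and, against the same hour, 634 and 1600 for butyrate 2 h, 734 and 1764 for aspirin 2 h and 491 and 1460 for aspirin 24 h. Lists passing went from 10 to 5 (butyrate), from 9 to 5 (between drugs) and from 11 to 5 (aspirin slopes) with quantile normalization, from 4 to 1 (aspirin) with the lower floor, and with an estimated correlation to 0 everywhere but in the butyrate slopes, where 1 was left. The correlation of both responses was 0.537 and the covariance excess 0.181 with the lower floor. Between the drugs, Acly, for the citrate lyase that feeds fatty acid synthesis, was 0.27 on one probe set (0.0397) and −0.041 with median centring, while its others read 0.74 (0.00714) and 1.06 (0.0192).

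With each array left out, the lowest and highest counts were 310 and 1166 (butyrate), 1 and 306 (aspirin), 241 and 1645 (between drugs), 81 and 541, 6 and 231, and 3 and 119 (slopes with butyrate, with aspirin, and their difference). Lists passing ranged from 7 to 12, 1 to 5, 7 to 12, 6 to 11, 4 to 11 and 2 to 7 in the same order, the correlation from 0.398 to 0.639 and the covariance excess from 0.00151 to 0.1997. Of the values named for each comparison, those never losing their call with another setting and with an array left out numbered 61 and 24 of 92 (butyrate), 12 and 13 of 19 (aspirin), 96 and 43 of 130 (between drugs), 15 and 8, 15 and 7, and 11 and 7 of 17 (slopes), uncalled values included, whose changes of sign were not counted. Over single lists and settings, 3067 results were as reported, 132 lost their call, 42 gained one and 1 turned: ribosomal proteins with butyrate, at 0.013 with quantile normalization (−0.17 as reported), where the call was lost too. Medians that turned without a call were not counted. Most of the 3067 were lists called neither as reported nor under the alternative, so that count says little of how stable the calls were.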

Other observations

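Comparisons of 1 array with 1 array at the same hour carry no test, and drug and array cannot be separated in them. Against the untreated array of the same hour, cell cycle genes had a median of −0.11 at 2 h and −1.50 at 24 h of butyrate, at percentiles 12.3 and 0.00 of random lists, and of −0.19 and −0.34 with aspirin (11.1 and 0.12). Enzymes of cholesterol and fatty acid synthesis were 1.19 higher after 2 h of butyrate (percentile 100) and −0.26 after 24 h (7.22).

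The untreated arrays themselves differed by list. From 2 to 24 h without drug, the median moved by 0.65 for cholesterol synthesis and 0.48 for antigen presentation (both at percentile 100), by 0.35 for oxidative phosphorylation (99.9), 0.31 for fatty acid oxidation (99.9) and 0.27 for blood and immune markers (99.2), and by −0.47 for histones (0.14) and −0.19 for ribosome biogenesis (2.48). The 3' to 5' signal ratio of actin, a sign of RNA integrity, was 1.55 on the aspirin 2 h array and 0.96 to 1.23 on the others. That of Gapdh was 1.19 and 1.31 on the untreated, 1.05 to 1.17 on the butyrate and 1.10 to 1.24 on the aspirin arrays, with the 1.10 on aspirin 2 h. The 99th percentile of intensity was 18987 to 21279 on the butyrate arrays and 21656 to 27350 on the others.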
